A study of Mus musculus with 2 samples.

How the data were processed

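Labelled RNA (Cy3, 1 colour) from dissected glomerular regions of diabetic mice was hybridised to an Agilent mouse expression array, with 1 array for wild-type mice (WT+STZ) and 1 for mice labelled as Sirt1-overexpressing (TG+STZ). The deposited scanner tables give for each spot a processed signal, its error and flags, as intensity on a linear scale. Per the file headers, the authors' scanner software was Agilent Feature Extraction 10.7.1.1, which subtracted background and corrected trends within each array. The submitters' processing notes name version 10.3.1.1 of the same software. The value table of the series held the same intensity as the scanner tables at each of 44397 spots of each array (deposited values equal, with no tolerance), with column medians of 158 and 162, so it had not been normalized between arrays. It was identified by matching its row names to the spot numbers.

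The main values were log2 of the processed intensity minus the 75th percentile of the gene probes of the same array. Control spots were left out, as were 114 and 109 gene spots that the software marked as outliers. Spots of 1 probe were averaged. Probes carry RefSeq or other accessions and were named through a RefSeq gene table of assembly GRCm38.p6. Of 39426 probes, 26410 matched a symbol and 13016 did not. The names cover 20017 genes. The order of neighbouring genes was taken from the same table. A probe entered only if it was well above background and not saturated on both arrays, and the probes of a gene were averaged. Of 4153 genes with several such probes, 1470 had probes on opposite sides of 0. The array design has no coordinates in the tables used here, and no genome was used, so positions in the genome are not given.

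The difference of each gene is TG+STZ minus WT+STZ on the log2 scale. Its error combines the software's error of both spots and is divided over the probes of the gene. Over all genes it ran from 0.08 to 0.45. The differences had a median of 0.00 and an SD of 0.26, and 95% of genes lay between -0.52 and 0.49. With 1 array per group no test, p-value or standard error between groups was computed. E1A spike-in probes, RNA added in known amounts, differed by -0.05 to 0.04 after scaling over the 8 probes well above background on both arrays. The dim probes E1A_r60_3 and E1A_r60_a104, mostly not above background, were left out and stood at -0.19 and 0.59. For a gene with no probe above background on both arrays and all its detected probes on the same array, the difference is a bound, taken against the higher of the dim probe's signal and the lowest signal above background on that array.

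The gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The text names Sirt1 and Cldn1, the 12 highest and 12 lowest genes brighter than the median gene whose probes lay on 1 side of 0, the 4 furthest members of each cell type list and of each list outside the band, the 2 furthest of the other lists, and the 3 largest bounds in each direction. Clone-like names were counted but not printed, and some genes that the rule takes are not reported here. A list's median was placed among 10000 random lists drawn from 20 signal bins, and lists beyond the outermost 2.5% on either side were said to lie outside the band. Other genes that are named were chosen after their values were seen.

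The alternatives were normexp background correction with an offset of 50, median centring, the 75th percentile over detected probes, quantile normalization, loess on signal with a span of 0.3, centring on the spike-ins, the value table, no filter on dim probes, genes brighter than the median gene alone, the brightest probe of each gene, a 1.5-fold threshold, counts without cell type markers, random lists of unmatched signal, lists without tubule genes or without their furthest member, and a laxer flag for detection. Normexp was run on spot medians, because the tables hold no spot means. Its offset pulls the differences of dim genes toward 0. After seeing the data, lists without fibroblast genes and counts without fibroblast and fat cell markers were added.

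The steps were tested on simulated data for the same comparison, with 200 of 16130 genes changed and a probe noise of 0.25. Genes simulated at log2 1.5 and -1.5 passed 2-fold in 100.0% and 97.0% of cases, those at 1 and -1 in 32.4% and 48.5%, and 0.0% of unchanged genes did. The noise had the same spread for bright and dim probes, so the 0.0% gives no rate of false calls for dim genes. All 4 shifted lists fell outside the band on the right side, and 2.5% of 200 random unshifted lists did. The simulated shifts were larger than the median of every real list outside the band except interferon response. Recovery of smaller shifts was therefore not tested. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.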

Results

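Gene expression was measured in kidney tissue of diabetic male mice with a C57BL/6J strain background. All mice received streptozotocin (STZ), a toxin of insulin-producing beta cells, at 8 weeks of age in 100 mmol/l citrate buffer and were killed at 32 weeks. RNA came from glomerular regions that had been dissected from the kidney. The glomerulus is the filtering unit of the nephron, and podocytes are the epithelial cells on its outer face. The WT+STZ array carried RNA of wild-type mice, and the TG+STZ array RNA of mice labelled as transgenic for overexpression of Sirt1, an NAD-dependent protein deacetylase. Each group had 1 array, so no difference has a replicate check and no test between groups was possible. The number of mice behind each array is not given in the sources used here. Both groups were diabetic, and no nondiabetic array was analysed here.

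Each array held 43020 spots of gene probes. Of these, 75.04% lay well above background on the WT+STZ array and 76.26% on the TG+STZ array, and none was saturated. The median processed signal was 173 and 180 intensity units. In all, 15975 genes had at least 1 probe well above background on both arrays. The arrays lay side by side on 1 slide and were read in 1 scan. The error printed with a gene is that of the scanner software and covers a single hybridisation. It was 0.20 on the log2 scale for the median gene and ran from 0.08 to 0.45, and errors of 0.20 to 0.21 are not repeated below. For bright genes with 1 probe it was nearly constant at 0.204, so it does not measure the scatter of each gene's own spots. It also leaves out disagreement between the probes of a gene. Spots of the same probe agreed more closely, with a median SD of 0.03 over 290 probes spotted 10 times. The number of arrays limits the precision, and neither error covers the spread between mice.

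The study asked how Sirt1 of the renal tubule relates to albumin loss and to claudin-1 in podocytes in diabetes. Sirt1 itself stood at 2625 intensity units on the WT+STZ array and 2977 on the TG+STZ array. The scaled log2 difference was 0.10 ± 0.20, within the error of the scanner. It rested on 1 probe. Whether that probe also reads the transgene is not given in the sources used here, so the value does not check the genotype labels. Cldn1, which encodes claudin-1, a tight junction protein, read 285 units in WT+STZ and 259 in TG+STZ. Its log2 difference was -0.22 ± 0.20, lower on the TG+STZ array by about the size of the error and also from 1 probe. The gene lists also hold Cldn1 as a marker of parietal epithelial cells, from the capsule around the glomerulus. Its value in mixed tissue cannot be assigned to podocytes. The other sirtuins lay close to 0, with a list median of 0.02 over 7 genes, at the 55.0th percentile of random lists. Sirt6 was furthest from 0 at -0.25 ± 0.15 (probes at -0.42 and -0.07), followed by Sirt5 at 0.14.

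Most genes had similar signals on both arrays. Among the brighter genes, Cish, a feedback inhibitor of cytokine and growth hormone receptors, was 4.88-fold higher on the TG+STZ array (log2 2.29), and Bcl6, a transcriptional repressor, was 5.17-fold lower (log2 -2.37). Irs2, an adaptor of the insulin receptor, was higher at 1.47. Scd1, which desaturates fatty acids, was higher at 1.25, and Gsta2, a glutathione transferase, was lower at -1.79. Of the 15975 genes, 83 were at least 2-fold higher and 75 at least 2-fold lower, and 99.0% lay under 2-fold. Under normexp the counts on the same genes were 36 and 29. Only 36 of the 2-fold genes were brighter than the median gene. Of the 158, 140 rested on a single probe each.

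The 12 highest of the brighter genes also held Jchain, the joining chain of secreted immunoglobulins, at 2.23, and Fcgbp, a mucus-associated protein, at 1.83. Gadd45g, a stress-response gene, stood at 1.42 and Cyp4a14, a fatty acid hydroxylase, at 1.40. The mitotic kinesins Cenpe and Kif20b stood at 1.44 and 1.36. Fam163a, Adat2, a tRNA deaminase subunit, and Syt10, a synaptotagmin, completed them at 2.16, 2.07 and 1.79. The 12 lowest held Fam20b, a kinase of proteoglycan synthesis, at -1.91, Npy, a neuropeptide, at -1.79 and Rad1, a checkpoint protein, at -1.46. Cyp26b1, which degrades retinoic acid, stood at -1.38, Atp4a, a proton pump subunit, at -1.29 and Nccrp1 at -1.17. Ces1g and Cyp2d34 stood at -1.12 and -1.096 ± 0.14, and both belong to families of similar genes whose transcripts can share a probe. The probes of Cyp2d34 stood at -1.66 and -0.53. Kyat3, a kynurenine aminotransferase, was at -1.66 ± 0.14, from probes at -2.33 and -0.98. F10, coagulation factor X, was at -1.33 ± 0.15, but its probes stood at -2.56 and -0.09, and the brighter probe was the one near 0. A further gene among the lowest had only a clone name. Fam163a and Fam20b lie in a stretch of chromosome 1 where 6 neighbouring genes were at least 2-fold apart.

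**Figure D1:**
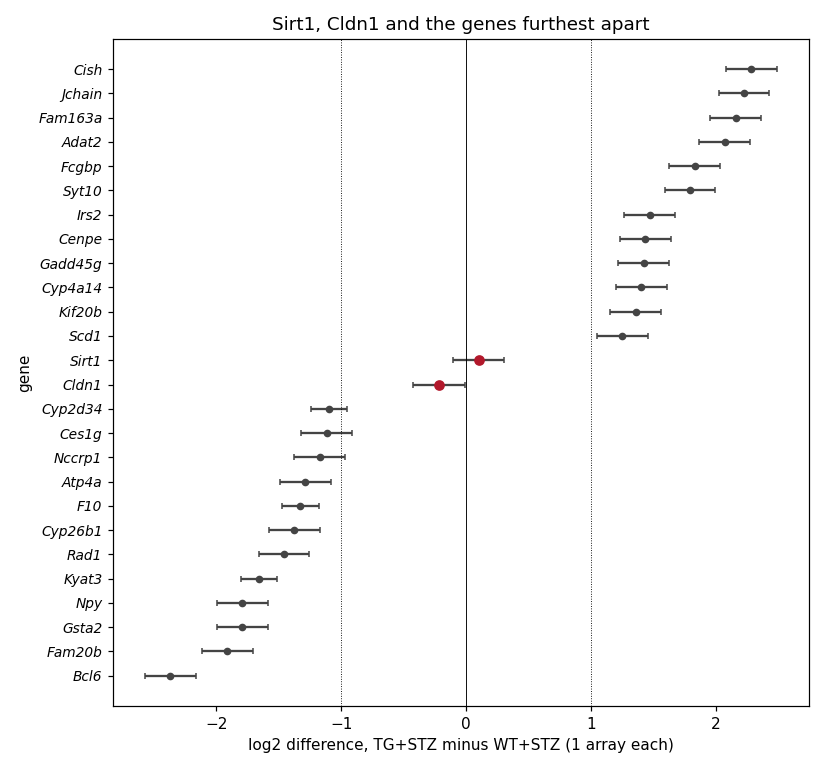
Log2 difference between the TG+STZ and the WT+STZ array (x axis, 1 array each) for Sirt1 and Cldn1 (red) and for the 12 highest and 12 lowest of the brighter genes (y axis). Bars show the error of the scanner software, dotted lines mark 2-fold, and Sirt1 at 0.10 and Cldn1 at -0.22 lie near 0, while Cish reaches 2.29 and Bcl6 -2.37.

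Some genes were well above background on a single array. In TG+STZ alone there were 319, and in WT+STZ alone 152, or 438 and 277 under the laxer detection flag. Of the 319 and 152, only 28 and 31 had a bound of 2-fold or more, so the larger count for TG+STZ is not seen among these genes. Synpr, a synaptic vesicle protein, was at least 97.3-fold higher in TG+STZ (6.94 against 1090 units). Ucp1, the uncoupling protein of brown fat, was at least 24.5-fold higher (3.63 against 274 units), and Adipoq, the hormone adiponectin of fat cells, at least 13.9-fold higher (7.07 against 156 units). In the other direction, the germ cell genes Ttll2 and Sycp1 were at least 5.94-fold and 4.87-fold lower in TG+STZ, and Prune2 at least 3.89-fold lower. Each bound sets the signal on the brighter array against the higher of the probe's signal on the other array and the lowest signal counted as above background there.

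The 37 gene lists fixed in advance were placed by their median difference among 10000 random lists of as many genes with matched signal. Of them, 7 lay in the uppermost 2.5% of their random lists, 15 in the lowermost 2.5% and 15 in the band between. About 1.85 would lie outside for lists of unrelated genes. Genes of a list vary together, so these positions describe the 2 arrays and not the genotypes. Of the 22 lists outside the band, 10 fell inside it under at least 1 other setting, namely parietal, mesangial, cytokine, claudin, vessel growth, glycolysis, endoplasmic reticulum stress, cholesterol synthesis, clock and sex-dependent genes. Other scalings also moved the medians of 10 of the 22 by over 1.5 times. Normexp background correction brought clock genes to 0.01, matrix genes to 0.03, cholesterol synthesis to 0.04, podocyte markers to -0.11, cytokines to -0.16 and glycolysis to -0.096, quantile normalization brought fatty acid oxidation to 0.07, sex-dependent genes to 0.03 and endoplasmic reticulum stress to -0.11, and loess brought antioxidant genes to 0.05. Median centring moved podocyte markers, glycolysis and endoplasmic reticulum stress the other way, to -0.04 each.

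Markers of glomerular cells were slightly lower on the TG+STZ array. Podocyte markers had a median of -0.06 (0.49th percentile), with 20 of 33 lower. Nphs1, which encodes nephrin of the slit diaphragm, was furthest at -0.89 (827 against 471 units). Trpc6 stood at 0.31 ± 0.29, and 13 of the 33 were higher, so the podocyte markers did not move as a block. Glomerular endothelial markers had a median of -0.08 (0.09th percentile), with Plat at -0.30, Sox17 at -0.26 ± 0.14 and Sox18 at -0.26, and Lpl, a lipase that fat also makes, at 0.35 ± 0.14. Mesangial and smooth muscle markers had a median of -0.09 (0.37th percentile), led by Acta2 at -0.35, Serpine2 at -0.34, Thy1 at -0.33 and Myh11 at -0.27. Parietal epithelial markers, from the capsule around the glomerulus, had a median of -0.08 (2.02nd percentile), with Prom1 at -0.41 ± 0.14, Akap12 at -0.31 and Cd44 at -0.26 ± 0.16 against Krt18 at 0.25. The probes of Akap12 stood at -0.55 and -0.06 and those of Cd44 at -0.45 and -0.06.

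Tubule markers were bright on both arrays, so the Sirt1, Cldn1 and glomerular marker values were measured in RNA that also held tubule transcripts. Podocyte markers were dimmer, with median signals of 1508 units in WT+STZ and 1513 in TG+STZ. Their median signal percentile among measured genes was 59.4, against 98.6 for proximal tubule markers. The signals alone do not show that glomerular cells were enriched. All 36 proximal tubule markers were well above background, with median signals of 85104 units in WT+STZ and 104035 in TG+STZ, and their median difference of 0.04 lay inside the band (34.4th percentile). Within the list G6pc, the last enzyme of glucose release, was lower at -0.68, as was Slc22a8, an organic anion transporter, at -0.56. Keg1 and Slc22a12, a urate transporter, were higher at 0.67 and 0.27. The more distal segments were lower. Loop of Henle markers had a median of -0.14 (14 of 18 lower, below all random lists), with Tmem207 at -0.60, Ptger3 at -0.38 ± 0.14 and Cldn19 at -0.28, and Sptssb at 0.45 ± 0.26. Distal convoluted tubule markers had a median of -0.12 (0.03rd percentile, 13 of 15 lower), with Trpv5 at -0.39, Emx1 at -0.31, Slc8a1 at -0.29 ± 0.16 and Trpm6 at -0.20. The probes of Slc8a1 stood at -0.61 and 0.03. Collecting duct markers were lowest of the cell type lists, with a median of -0.25 (16 of 21 lower, below all random lists). Kcne1 was at -0.98 ± 0.29, and the intercalated cell genes Slc26a4, Insrr and Slc4a9 at -0.63, -0.63 and -0.56 ± 0.14.

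Genes of the interferon response and of white blood cells were lower on the TG+STZ array. Of 31 interferon-response genes 29 were lower, with a median of -0.34, below all random lists. Oas2 and Oas1a, which sense viral RNA, stood at -1.11 and -0.88 ± 0.14, the RNA sensor Ifih1 at -0.93 and Usp18, a brake on interferon signalling, at -0.73. Of 32 leukocyte markers 30 were lower, with a median of -0.15 (0.02nd percentile). The B cell gene Ms4a1 stood at -0.79, the neutrophil genes S100a9 and S100a8 at -0.76 and -0.64, and the T cell gene Cd8a at -0.66. Cytokines and adhesion molecules had a median of -0.09 (0.70th percentile), with the chemokines Ccl2, Ccl5 and Ccl4 at -1.12, -0.98 and -0.84 and Ccl8 at 0.90. Over the 12 of these genes that were brighter than the median gene, the list lay inside the band. Red cell and plasma cell markers had a median of -0.17 (0.02nd percentile), with Alas2 at -0.29, Mzb1 at 0.25, Slc4a1 at 0.22 and Jchain far apart at 2.23.

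Connective tissue genes were higher on the TG+STZ array. Fibroblast and adventitial markers had a median of 0.25, above all random lists, with 14 of 17 higher. They included Clec3b at 1.096 ± 0.24, Igfbp6 at 0.61, Dpt at 0.59 ± 0.22 and Mfap5 at 0.56. Matrix and fibrosis genes had a median of 0.08 (30 of 43 higher, above all random lists) and 0.03 under normexp, among them the growth factor Ccn2 at 0.56, Col1a1 at 0.53 and Mmp2 at 0.51. Fat cell genes moved the same way: 16 of 16 further fat cell markers, chosen after Ucp1 and Adipoq had been seen, were higher, with a median of 0.51. Under normexp 11 of the 16 were higher, with a median of 0.196. Cfd, a protease secreted by fat cells, stood at 4.82 ± 0.22 (41.2 against 1225 units).

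Lipid metabolism genes were higher as well. Whether the fat cell transcripts described above contribute to the lipid values was not tested. Fatty acid oxidation genes had a median of 0.12 (32 of 43 higher, above all random lists), with Cyp4a14 at 1.40, Cyp4a12a at 0.98 and Angptl4, an inhibitor of lipoprotein lipase, at 0.97, and Fabp1 lower at -0.88. Cholesterol and fatty acid synthesis had a median of 0.07 (98.3rd percentile), with Scd1 at 1.25, Sc5d at 1.22 and Idi1 at 0.49. Without Scd1 that list lay inside the band. Antioxidant genes had a median of 0.09 (99.7th percentile, 27 of 34 higher), with Ucp2 at 0.49, Gstm2 at 0.47 ± 0.12 and Nqo1 at 0.22 and Gsta2 opposite at -1.79. Glycolysis genes had a median of -0.06 (0.29th percentile), with Slc16a3 at -0.46 ± 0.15, Pfkp at -0.24 ± 0.15, the glucose transporter gene Slc2a1 at -0.22 and Aldoc at -0.21. The call of the glycolysis list was lost against random lists of unmatched signal.

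Clock genes were split. Their list had a median of 0.21, above all random lists, with 12 of 21 higher and 9 lower, but the median was 0.01 and inside the band under normexp. Dbp, a clock output gene, was at 1.16 ± 0.14 and Ciart at 0.98 ± 0.27, while Cry1 stood at -0.85 ± 0.28 and Arntl, which encodes BMAL1, at -0.70. Genes that differ between male and female kidneys had a median of 0.10 (99.6th percentile), with Abcc3 at 1.65, Cyp4a14 at 1.40 and the organic anion transporter Slco1a1 at 1.20, and Prlr, the prolactin receptor gene, at -1.31 ± 0.14. Under quantile normalization this list lay inside the band. It mixes genes higher in males with genes higher in females, so its median points to neither sex.

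The remaining lists below the band moved little. Claudins had a median of -0.09 (1.55th percentile, 14 of 19 lower), led by the dim genes Cldn6, Cldn22 and Cldn11 at -0.86 ± 0.24, -0.44 ± 0.23 and -0.38, with Cldn3 at 0.30. The claudin list was inside the band under 3 other settings. Endoplasmic reticulum stress genes had a median of -0.06 (0.10th percentile), with the secretory chaperone genes Sdf2l1, Creld2 and Manf at -0.79, -0.58 and -0.58 and Asns at 0.63. Vessel growth and nitric oxide genes had a median of -0.07 (0.36th percentile), with Tie1 at -0.25 and Nrp1 at -0.22 against Angptl4 at 0.97 and Ddah1 at 0.58 ± 0.14.

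The other lists lay inside the band. NAD metabolism had a median of 0.03 (64.0th percentile), with Kynu at -1.04 ± 0.15 and Nnmt at 0.65. Other tight junction genes had a median of -0.02 (15.3rd percentile), with Cgnl1 at -0.26 and Pard6b at -0.20. DNA methylation and histone modifiers had a median of 0.03 (88.1st percentile), with Dnmt3l at 0.48 and Tet2 at -0.30 ± 0.14. SIRT1 substrates had a median of -0.02 (13.3rd percentile), with Foxo3 at -0.72 ± 0.23 and Arntl at -0.70. Injury markers had a median of 0.05 (90.1st percentile), with Krt20 at 1.19 ± 0.26 and Ccl2 at -1.12. Oxidative phosphorylation had a median of 0.07 (91.9th percentile), and 38 of its 40 genes were higher, led by Cycs at 0.25 ± 0.12 and Cox6b1 at 0.16. Glucose production and transport had a median of 0.04 (66.6th percentile), with Irs2 at 1.47 and G6pc at -0.68. Immediate early and heat shock genes had a median of -0.05 (2.74th percentile), with Dusp1 at 0.93 and Hspb1 at -0.57. Autophagy genes had a median of 0.01 (25.9th percentile), with Atg3 at 0.15 and Bnip3 at 0.13 ± 0.12. Cell cycle genes had a median near 0 (67.9th percentile), with Cenpe at 1.44 and Kif11 at -1.06 ± 0.26. Apoptosis and p53 target genes had a median of 0.03 (74.96th percentile), with Sesn1 at -0.37 and Bak1 at 0.37. The renin-angiotensin and endothelin list had a median of 0.01 (49.6th percentile), with Hsd11b1, which regenerates active glucocorticoid, at 1.05 and Npr1 at -0.33. Reference genes had a median of 0.02 (29.0th percentile), with Gusb at 0.57. Medians this close to 0 changed sign under some scalings, namely for proximal tubule markers, sirtuins, other tight junction genes, histone modifiers, SIRT1 substrates, injury markers, autophagy, cell cycle, apoptosis, renin-angiotensin and reference genes.

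**Figure D2:**
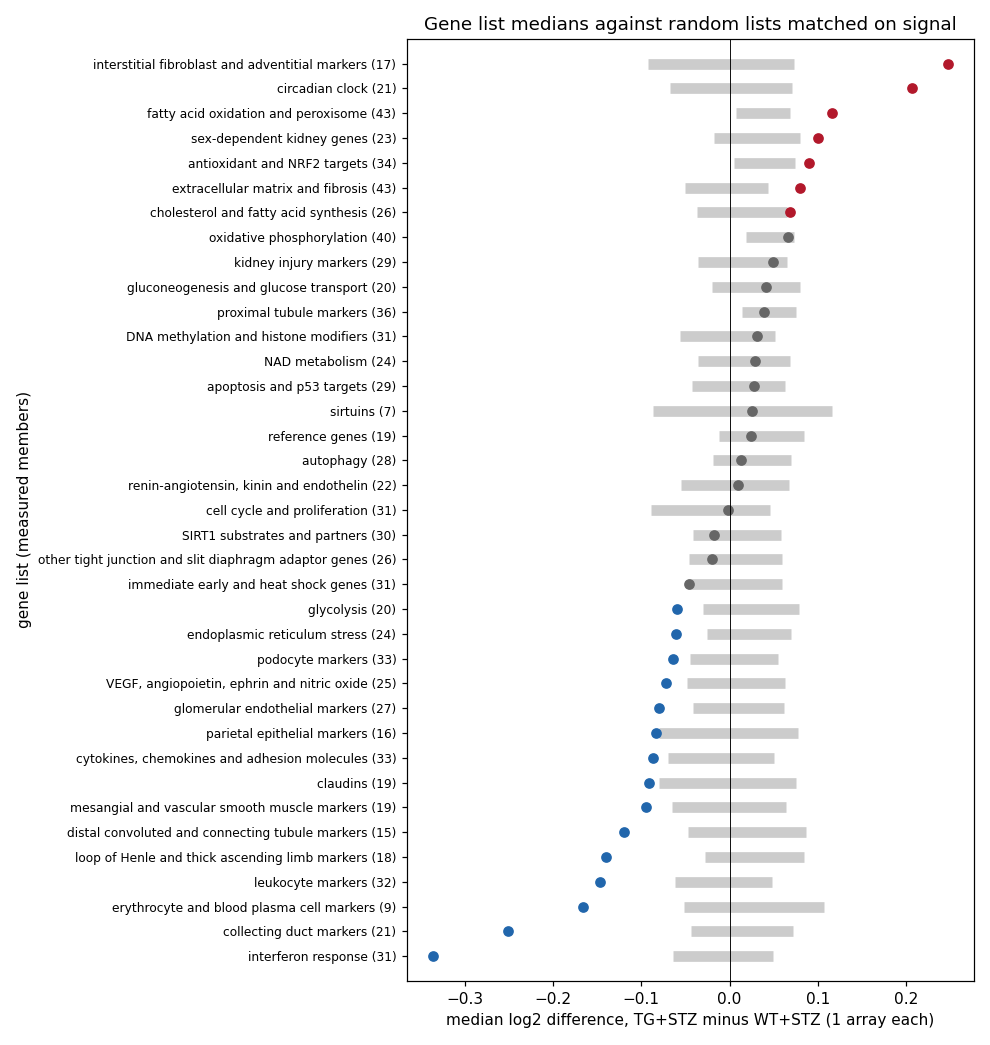
Median log2 difference between the TG+STZ and the WT+STZ array (x axis, 1 array each) for each of the 37 gene lists (y axis, measured members in brackets), as points coloured red above, blue below and grey inside the band. Grey bars span all but the outermost 2.5% on each side of 10000 random lists of matched signal, and the interferon response list lies furthest below at -0.34 and the fibroblast list furthest above at 0.25.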

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

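The signals below lie in spots that the comparison of named genes did not use, and all were looked at after the main values were known. Among 8055 probes with no gene symbol here that were well above background on both arrays, 120 were at least 2-fold higher on the TG+STZ array and 47 at least 2-fold lower, or 1.49% and 0.58%. Among named probes the shares were 0.49% and 0.45%. A control probe with 10 spots, ETG05_66023, had a median log2 difference of 0.81, higher on the TG+STZ array. It was dim, at 22.8 units in WT+STZ and 41.2 in TG+STZ. The lowest signals counted as above background were 10.6 and 9.70 units.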

How the results depend on the processing

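Values of single genes were compared with the scanner error, since there are no replicates. Sirt1 and Cldn1 stayed within that error of 0.10 and -0.22 under each alternative that gave a value, and Cldn1 gave none among genes brighter than the median gene. No named gene at least 2-fold apart changed sign under any alternative. Of 133 named genes, 31 moved by more than their scanner error under at least 1 alternative. The value table moves nothing, being equal to the scanner signal. Across scalings the median gene moved by at most 0.05 on the log2 scale. Of the 22 lists outside the band, 12 stayed outside under every alternative run, and of the 15 inside, 4 left it under at least 1. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes, and unless said otherwise the cause of a change was not tested.

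The counts of genes at least 2-fold higher and lower were 36 and 29 under normexp, which changed the background correction and used spot medians, 295 and 323 without the filter on dim probes, and 21 and 15 among genes brighter than the median gene, where fewer genes are counted. At 1.5-fold they were 280 and 305. Under the laxer detection flag, genes above background in WT+STZ alone numbered 277 in place of 152.

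Lists that entered the band are given by percentile. Under normexp these were vessel growth genes at 2.83, cholesterol and fatty acid synthesis at 96.3, clock genes at 95.9 and claudins at 10.65. Claudins were also inside under loess at 2.77 and without the filter at 3.67. Among genes brighter than the median gene cytokines were at 11.2 and parietal markers at 3.50. Against random lists of unmatched signal, endoplasmic reticulum stress was at 4.25, glycolysis at 5.64 and parietal markers at 3.29. Without their furthest member, cholesterol synthesis was at 94.6, mesangial markers at 2.90 and parietal markers at 4.28. With the brightest probe parietal markers were at 3.04, and under quantile normalization the sex-dependent genes at 90.4. Lists that left the band were glucose production at 97.8 without tubule genes, immediate early genes at 1.93 without the filter and 1.93 without their furthest member, injury markers at 98.7 with the brightest probe, and oxidative phosphorylation at 97.51 among genes brighter than the median gene, 99.2 under quantile normalization and 99.5 against unmatched lists.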

Other observations

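The genes in this paragraph were picked after their values were seen, so they stand for no wider group. Socs2, like Cish a feedback inhibitor of growth hormone signalling, was higher in TG+STZ at 0.81 ± 0.12 over 3 probes, and Igf1 stood at 0.31 ± 0.10 over 4 probes. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 0.89 ± 0.12, and Socs3, a feedback inhibitor in inflammation, at -0.10. The uroplakin genes Upk1a, Upk1b, Upk3a and Upk2 stood at 1.16, 0.88, 0.68 and 0.63. Among genes of the exocrine pancreas, Sycn stood at -1.45, Cpb1 at -1.76 ± 0.34 and Amy2a5 at -0.96 ± 0.15, but Ctrb1 at -0.27 and Clps at -0.10. The chemokine gene Ccl28 stood at 2.48 and the growth factor gene Fgf10 at -2.04 ± 0.22.

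Of the tests below, those of unseen fat cell markers and of the spread among neighbouring genes were set down before their values were looked up. All others were chosen after the result was seen.

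Fat cell and connective tissue transcripts were higher on the TG+STZ array. Of 19 fat cell markers not looked up before, 16 were measured and all 16 were higher, with a median of 0.51, just above the 0.5 set beforehand, but 0.49 with the 75th percentile of detected probes, 0.196 (11 of 16 higher) under normexp and 0.34 over all 19 without the filter on dim probes. A median below 0.2 had been set beforehand as going against fat tissue, and the normexp value lay just below it. Normexp adds an offset of 50, which shrinks the differences of dim markers such as Adrb3 (20.6 units in WT+STZ). The normexp value therefore does not decide against fat tissue. Cfd stood at 4.82 ± 0.22, Cox8b at 2.93 ± 0.23, Cidea at 2.90 and Retn at 2.84 ± 0.24, but Fabp4, Car3 and Cox7a1, already above 10000 units in WT+STZ, at 0.34, 0.13 and 0.02, Lipe and Cpt1b, without such a baseline, at 0.03 and 0.05 ± 0.14, and Lep, Elovl3 and Acvr1c were not well above background on either array. For the fibroblast list a smooth scale difference between dim and bright spots is argued against, since the list lay above all random lists of matched signal. Loess, which left the list at 0.24, adds little to that placing. Fat around the kidney in the TG+STZ tissue, which a clean dissection of glomeruli would leave out, is a candidate explanation that stays open, and an effect of the transgene was not tested.

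The 2-fold genes were crowded in a stretch of chromosome 1. A window of 50 neighbouring measured genes, in the order of the RefSeq table, held 6 of them (among them Fam163a at 2.16, Soat1 at -1.23, Fam20b at -1.91, Pappa2 at 1.26 and Tnn at -1.12), against 0.49 per window on average, and 1.52% of 10000 shuffled gene orders held a window as full. As 50% of the 6 were higher, a gain or loss of copies, which moves genes 1 way, is argued against. The other genes of the window had an SD of 0.29, wider than in 97% of 300 windows, which is consistent with a stretch from another mouse strain that differs between the arrays, as a hypothesis. The window was chosen after it had been seen.

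Clock genes differed by phase. Of 12 genes switched on by CLOCK and BMAL1, 10 were higher (median 0.31), and of 6 genes of the opposite phase 4 were lower (median -0.29), a gap of 0.60, or 0.50 under normexp. Hlf at -0.45, Bhlhe41 at -0.20 ± 0.38, Nfil3 at 0.49 and Clock at 0.00 went against their group or did not move. Noise of dim genes stays open, since over the 6 and 3 genes brighter than the median gene the gap was 0.34 ± 0.23 (scanner error). Mice killed at different times of day are a candidate explanation, and the transgene acting on the clock cannot be told apart from it, with 1 array per genotype.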
